A study of Homo sapiens with 6 samples.

How the data were processed

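Gene expression was measured on 6 Illumina whole-transcriptome bead arrays, 1 per sample, in human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein. Per the labels, cells grown in endothelial medium were transfected with siRNA for 72 h, and total RNA was labelled with a single dye. The labels and the design text set 3 groups of 2 arrays each: control siRNA, siRNA against apelin (APLN) together with its receptor APJ (APLNR), and siRNA against FOXO1. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

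The authors deposited a table of intensity values for 47321 probes on all 6 arrays, on a linear scale. Its 6 columns had nearly the same distribution (medians of 116.134 to 116.164, maximum 23344.9 on each), as quantile normalization gives, with no background subtracted; the normalization software is not given in the sources used here. A second deposited table held scanner intensity, not normalized per the file headers, and a detection p-value for each probe. Its column names tied 2 of its 6 arrays to samples through the labels, both of them FOXO1 siRNA arrays, and the other 8 columns of per-array values were not used. On those 2 arrays the scanner signal ranked the probes as the deposited value did (rank correlation 1 for both), so the value table was taken as a normalized form of the scanner signal. The scanner headers named 1 slide, so slide could not be tested as a batch. The labels give no other batch, and whether all 6 samples were processed together is not given in the sources used here.

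The design written before the data were examined named background correction with negative controls or detection p-values (limma neqc). That needs scanner values for every array, so the alternative named there was used: normexp background correction with an offset of 50, then quantile normalization and log2, on the value table. A probe was taken as above background on an array at a deposited intensity of at least 122.169, the level at which the detection p-value of FOXO1 siRNA replicate 1 passed 0.05 (128.399 for 0.01). It was kept if it reached that level on at least 2 of the 6 arrays, whatever their group. This threshold comes from a single array and applies to the others only through their shared distribution. Per array, 19167 to 19194 probes reached it (40.5% to 40.6%), and 10923 to 11006 genes. Since the values share a distribution and 1 threshold was used, these counts are nearly equal by construction and say nothing of the depth of single arrays. The number of arrays limits the precision.

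Gene symbols came from the platform annotation supplied with the table. Of the probes, 30112 had 1 symbol, 8 had several and 17201 had none; 30073 of the first were found by gene identifier in a RefSeq gene table, which changed 0 symbols. No gene was named from a probe with several symbols. XIST and Y-linked genes (144 probes) were left out, leaving 19951 genes. Filtering kept 21031 probes. Each gene was represented by the probe with the highest mean over all 6 arrays, which gave 11886 genes, and where another probe of a gene named in the report went against it this is said. All levels are normalized log2 intensities.

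One limma model of 3 group means was fitted to all 6 arrays (lmFit and eBayes, 3 residual degrees of freedom and 6.04 prior degrees of freedom), with no covariates. The 2 knockdowns were each compared with control siRNA and with each other, two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene counted as changed at an adjusted p under 0.05. Errors of fold changes are standard errors of log2 values from this model. The model gives the 3 groups the same spread per gene, though the control arrays varied more than those of the knockdowns. Errors and p-values against control may therefore be too small, and those between the knockdowns too large. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is reported. A gene not above background on either array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dimmer group's mean, with each dim array set to the higher of its own value and the lowest signal counted as above background. No fold is given where both groups were below background.

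The text names APLN, APLNR and FOXO1, and for each knockdown the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap (10 and 10 between the knockdowns). It also names up to 4 members of smallest p per gene list, up to 8 genes for each class changed in opposite directions by the knockdowns and up to 4 for each class changed in the same direction. Except where said below, this rule, the tests, the alternatives and 33 gene lists were fixed before the data were examined. The lists cover FoxO targets, endothelial genes linked to FOXO1, fatty acid uptake and oxidation, cholesterol synthesis, G1/S and G2/M cell cycle, endothelial identity, tip cells, Notch and arterial genes, venous and lymphatic genes, and the KLF2 and MEF2 axis. They also cover FGF signalling, vasoactive mediators, NF-kB inflammatory genes, interferon response, p53 targets, endoplasmic reticulum stress, the ATF4 response, hypoxia, glycolysis, oxidative phosphorylation, MYC and ribosome biogenesis, and ribosomal proteins. The rest cover YAP/TAZ targets, TGF-beta and mesenchymal transition, basement membrane, autophagy and lysosome, immediate early genes, heat shock, and markers of smooth muscle cells or fibroblasts, blood cells and epithelium. Lists were tested with camera (preset inter-gene correlation 0.01, at least 5 tested members), adjusted over the 33 lists. For each list that passed, the adjusted p with an estimated correlation is also given, and none of them passed with it in any of the 3 comparisons. That correlation is estimated from 3 residual degrees of freedom, which leaves the test little power. The G2/M list, with 37 of 38 members higher with FOXO1 siRNA, reached 0.0612. A list that did not pass with it is therefore not shown to be unchanged.

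Both knockdowns share the control arrays, so their fold changes correlate by chance. This was gauged with 100 simulated sets of unchanged groups against shared controls, using the model's moderated SDs. The control arrays varied more than those of the knockdowns, so a further 100 sets, chosen after seeing the data, used each group's own SDs per gene. The 2 control arrays could not be split into parts of at least 2. Fold changes against a separate control array for each knockdown, also chosen after seeing the data, are given as values with no significance test.

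The gene test was checked on simulated data with 200 of 11886 genes changed in 1 knockdown, over 10 draws. A first version drew noise from the model's moderated SDs; its fitted prior degrees of freedom, 12.4 to 18.1 for APLN/APLNR siRNA and 12.3 to 19.2 for FOXO1 siRNA, lay above those of the real data. Its mean share of false calls was 6.18% for APLN/APLNR siRNA against control and 8.04% for FOXO1 siRNA against control. A second version, added after that was seen, drew SDs from the prior that the real data gave. Its prior degrees of freedom were 5.29 to 6.17 and 5.67 to 6.67. Mean shares of false calls were then 4.73% (3.60% to 7.59%) and 5.15% (2.72% to 11.1%). In that version a true log2 change of 0.5 was found for 20.3% of genes with APLN/APLNR siRNA and 19.1% with FOXO1 siRNA. The shares were 93.7% and 95.4% for a change of 1, and 100% in both for a change of 2. Both versions gave all groups equal SDs and changed few genes, unlike the real data, so these shares may not carry over. In a further simulation for APLN/APLNR siRNA, run as 1 draw, camera passed the 1 list shifted by 0.5 and 0 of the 32 others. Its noise was independent between genes, so it does not show whether the preset correlation holds for these lists.

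Alternatives changed the background correction, normalization, filter on dim probes, use of probes, variance model, arrays in the fit and inter-gene correlation, added a replicate block, or left out each array in turn. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.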

Results

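The series profiled gene expression in human umbilical vein endothelial cells 72 h after transfection with control siRNA, with siRNA against apelin (APLN) and its receptor APJ (APLNR) together, or with siRNA against the transcription factor FOXO1. Each group had 2 Illumina arrays. Replicates correlated at 0.985 for control siRNA, 0.996 for APLN/APLNR siRNA and 0.997 for FOXO1 siRNA, across genes, which are not independent replicates. The median SD between replicates was 0.123 log2 units for control siRNA, 0.0745 for APLN/APLNR siRNA and 0.0593 for FOXO1 siRNA. Between the 2 control arrays 52 genes differed by over 2-fold, against 0 genes in each knockdown.

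The targets were measured first. APLN, which encodes the secreted peptide apelin, was at 12.10 ± 0.45 (SD, n = 2) with control siRNA, 9.26 ± 0.11 (SD, n = 2) with APLN/APLNR siRNA and 10.63 ± 0.07 (SD, n = 2) with FOXO1 siRNA. It fell 7.17-fold with APLN/APLNR siRNA (adjusted p = 5.4e-05) and 2.77-fold with FOXO1 siRNA (adjusted p = 5.85e-04). FOXO1 was at 9.11 ± 0.21 (SD, n = 2) with control siRNA and fell 2.09-fold with FOXO1 siRNA, to 8.04 ± 0.04 (SD, n = 2; adjusted p = 4.16e-04). With APLN/APLNR siRNA its level was 9.48 ± 0.08 (SD, n = 2), and the difference from control did not pass (log2 fold change 0.38, SE 0.12, adjusted p = 0.0640). APLNR was below background on the arrays of control siRNA and APLN/APLNR siRNA, so its knockdown could not be measured. On both FOXO1 siRNA arrays it was above background, at least 1.07-fold over control siRNA (adjusted p = 0.0672) and at least 1.07-fold over APLN/APLNR siRNA (adjusted p = 0.0358). Each target had 1 probe.

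**Figure D1:**
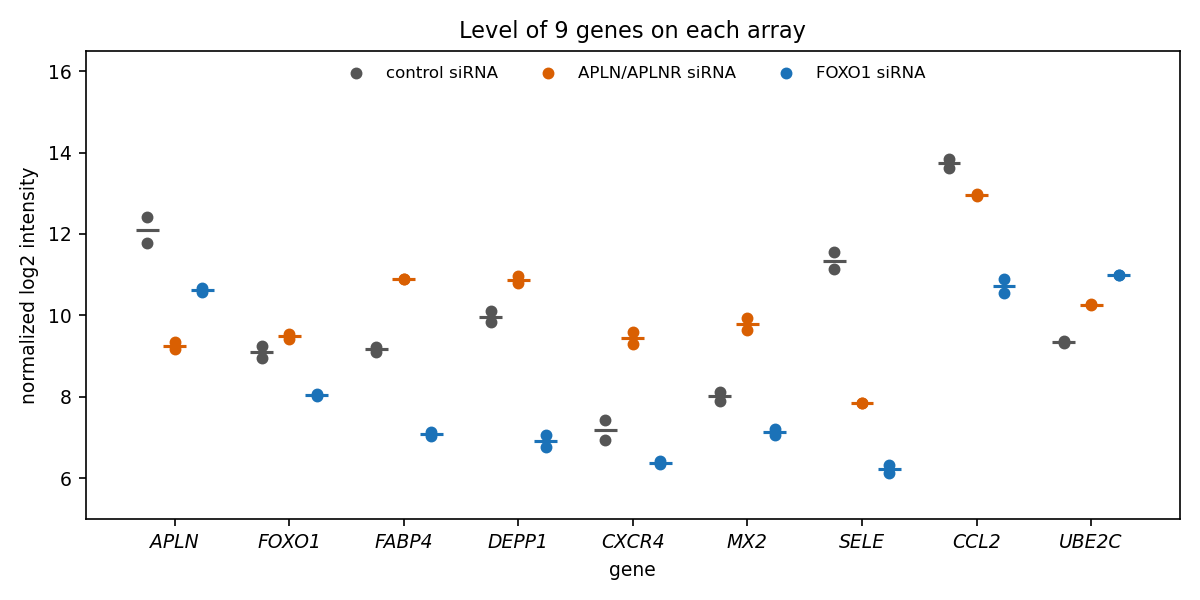
Normalized log2 intensity (vertical axis) of 9 genes on each of the 6 arrays; points are arrays, horizontal lines are group means and colours are the siRNA groups. APLN lies at 12.4 and 11.8 with control siRNA, 9.18 and 9.33 with APLN/APLNR siRNA and 10.6 and 10.7 with FOXO1 siRNA, and SELE on the FOXO1 siRNA arrays is below background.

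The comparison of APLN/APLNR siRNA with control siRNA asks which genes depend on endothelial apelin signalling (n = 2 arrays per group). Of 33 lists 9 passed, and 0 with an estimated correlation, with inflammatory and adhesion genes among those lower and interferon response genes among those higher. SELE, encoding the leukocyte adhesion molecule E-selectin, fell 11.3-fold (SE 0.15 on the log2 scale), the cytokine gene LTB 7.39-fold (SE 0.17) and the chemokine gene CCL20 6.96-fold (SE 0.12). The interferon-induced genes IFI6 and MX2 rose 3.71-fold (SE 0.13) and 3.41-fold (SE 0.13). The fatty acid binding protein gene FABP4 rose 3.31-fold (SE 0.11) and the chemokine receptor gene CXCR4 4.81-fold (SE 0.17). In all, 2390 of 11886 genes changed (20.1%), 1235 higher and 1155 lower, with 120 higher and 151 lower by over 2-fold. At an unadjusted p under 0.05 there were 3934. With only the arrays of these 2 groups in the fit, 1539 genes passed the adjusted threshold.

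The other large rises were those of LYPD1 (6.92-fold), the chemokine gene CCL23 (6.85-fold), SPOCD1 (5.63-fold), RASD1 (3.83-fold), RNF213 (3.73-fold, with another probe that did not pass), PIP5K1C (3.33-fold), TXNIP, which encodes an inhibitor of thioredoxin (3.28-fold), and AP1M1 (3.27-fold). After SELE, LTB, APLN and CCL20, the deepest falls were those of PLVAP, which encodes a protein of the diaphragms of endothelial caveolae and fenestrae (6.40-fold), CYTL1 (6.15-fold) and the chemokine gene CX3CL1 (5.80-fold). They continued with SUMF1 (4.71-fold), MSMP (4.44-fold), the ganglioside synthesis gene ST3GAL5 (4.44-fold), VIP (4.39-fold) and CXXC5 (4.35-fold). The adjusted p of these 24 genes, with APLN among them, ran from 5.45e-06 to 4.6e-04, and their SE from 0.10 to 0.22. By the rule that picked these genes, both arrays of 1 group lay beyond both of the other for each of them. Groups were apart in this way for 6700 genes in all (56.4%), where chance gives 33.3% for a single gene. Since all genes share the same arrays, the share over genes can depart from this value without an effect of the siRNA.

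With the preset correlation, the interferon response had the smallest adjusted p of the lists with APLN/APLNR siRNA. Of 33 tested members 24 rose, 0 fell and 9 did not pass, or 25 changed when adjusted over the list alone, with a median log2 fold change of 0.76 (camera adjusted p = 2.2e-15). The adjusted p was 0.248 with an estimated correlation. IFITM1 (2.85-fold) and EPSTI1 (2.28-fold) rose beside IFI6 and MX2. In the NF-kB inflammatory and adhesion list 11 of 21 members fell, 0 rose and 10 did not pass, or 14 changed when adjusted over the list alone, with a median of -0.44 (adjusted p = 8.21e-08, and adjusted p = 0.161 with an estimated correlation). CXCL2 (2.83-fold) and VCAM1 (3.12-fold), a leukocyte adhesion molecule, fell with SELE and CCL20.

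Both cell cycle lists passed with APLN/APLNR siRNA, with part of their members higher. In the G2/M list 23 of 38 members rose, 0 fell and 15 did not pass, or 30 changed when adjusted over the list alone, with a median of 0.47 (adjusted p = 2.74e-10, and adjusted p = 0.161 with an estimated correlation). The mitotic kinase genes AURKB (1.82-fold) and AURKA (1.57-fold) rose, as did DLGAP5 (1.61-fold) and UBE2C (1.91-fold, with another probe that did not pass). In the G1/S list 9 of 31 members rose, 0 fell and 22 did not pass, or 10 changed when adjusted over the list alone, with a median of 0.25 (adjusted p = 0.00639, and adjusted p = 0.646 with an estimated correlation). The replication genes MCM5 (1.45-fold) and TYMS (1.62-fold) were among them, and both lost their call without either of the APLN/APLNR siRNA arrays (adjusted p up to 0.0686 and 0.0936).

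Endothelial identity genes moved both ways with APLN/APLNR siRNA. Of 32 members 10 fell, 3 rose and 19 did not pass, or 19 changed when adjusted over the list alone, with a median of -0.29 (adjusted p = 0.00962, and adjusted p = 0.646 with an estimated correlation). PLVAP and CD34 (1.82-fold, with another probe that did not pass) fell, while ENG, which encodes the co-receptor endoglin, rose 1.88-fold. The list of markers of smooth muscle cells and fibroblasts passed in the other direction, higher with APLN/APLNR siRNA. Of the 7 tested, 4 rose, 1 fell and 2 did not pass, or 6 changed when adjusted over the list alone (median 0.42, adjusted p = 0.0280, and adjusted p = 0.436 with an estimated correlation). COL1A2 rose 2.08-fold, DCN at least 1.36-fold and TAGLN 1.73-fold, while RGS5 fell 1.76-fold. The other probes of TAGLN did not pass (log2 fold changes 0.0959 and 0.280). The calls on TAGLN and RGS5 were lost without either APLN/APLNR siRNA array (adjusted p up to 0.0633 and 0.148). Blood cell markers (1 lower and 0 higher of 6, adjusted p = 0.494) and epithelial markers (1 higher and 1 lower of 8, adjusted p = 0.614) did not pass. The call on the smooth muscle and fibroblast list was lost without control replicate 2 and with no filter on dim probes (adjusted p up to 0.132).

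Lists of sterol synthesis and stress responses also passed with APLN/APLNR siRNA. In the cholesterol synthesis list 7 of 19 members fell, 1 rose and 11 did not pass, or 10 changed when adjusted over the list alone (median -0.32, adjusted p = 0.0324, and adjusted p = 0.646 with an estimated correlation). SC5D fell 2.19-fold and TM7SF2 1.91-fold. LSS rose 1.68-fold by the probe used, while its other probes did not pass (log2 fold changes -0.0169 and -0.109). The list did not pass with a stricter filter, without control replicate 2 or without APLN/APLNR siRNA replicate 1 (adjusted p up to 0.102). In the endoplasmic reticulum stress list 3 of 17 members fell, 1 rose and 13 did not pass, or 11 changed when adjusted over the list alone (median -0.32, adjusted p = 0.00639, and adjusted p = 0.351 with an estimated correlation). DNAJC3, a chaperone gene, fell 1.61-fold, a call lost without either APLN/APLNR siRNA array (adjusted p up to 0.0584). In the ATF4 amino acid response list 6 of 19 members rose, 2 fell and 11 did not pass, or 14 changed when adjusted over the list alone (median 0.36, adjusted p = 0.0324, and adjusted p = 0.646 with an estimated correlation). CEBPB rose 2.09-fold and the cystine transporter gene SLC7A11 1.75-fold, while VLDLR fell 1.75-fold. Without control replicate 1 the list did not pass (adjusted p = 0.0680).

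The FoxO target list did not pass with APLN/APLNR siRNA. Of 32 members 9 rose, 0 fell and 23 did not pass, or 10 changed when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0630, and adjusted p = 0.662 with an estimated correlation). TXNIP, FBXO32 (2.32-fold), a ubiquitin ligase gene, and GADD45B (2.13-fold) rose, as did DEPP1 (1.88-fold), whose call was lost without APLN/APLNR siRNA replicate 2 (adjusted p = 0.0506). The list passed without control replicate 1 (adjusted p = 0.0189) and with no filter on dim probes (adjusted p = 0.0287), and over the alternatives with the preset correlation its adjusted p ran from 0.0189 to 0.233. The count of changed genes in this comparison was 4419 without control replicate 2, 765 and 705 without APLN/APLNR siRNA replicates 1 and 2, and 1539 without either FOXO1 siRNA array or with only the arrays compared.

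The comparison of FOXO1 siRNA with control siRNA asks which genes depend on FOXO1 (n = 2 arrays per group). Of 33 lists 15 passed, and 0 with an estimated correlation, with inflammatory, arterial and tip cell genes among those lower and cell cycle genes among those higher. SELE fell at least 31.9-fold to below background (SE 0.15 on the log2 scale), CX3CL1 10.2-fold (SE 0.21) and CCL2, which encodes a monocyte chemokine, 8.13-fold (SE 0.14). The gap junction gene GJA4 fell at least 8.93-fold (SE 0.14) and the FoxO target DEPP1 8.33-fold (SE 0.14). IL1RL1, which encodes the receptor of the cytokine IL33, rose 10.7-fold (SE 0.13), while IL33 itself fell 6.67-fold (SE 0.12). In all, 3454 genes changed (29.1%), 1682 higher and 1772 lower, with 217 higher and 271 lower by over 2-fold. At an unadjusted p under 0.05 there were 4781. With only the arrays of these 2 groups in the fit, 2616 genes passed the adjusted threshold.

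Beyond these, the deepest falls with FOXO1 siRNA were those of CYTL1 (10.9-fold), LTB (at least 8.08-fold), CXCL2 (7.85-fold), the cytokine gene IL1A (6.92-fold) and the neutrophil chemokine gene CXCL8 (6.72-fold). CCL20 fell by 3.32 on the log2 scale. The largest rises after IL1RL1 were those of RGS4, a regulator of G protein signalling (4.50-fold), LYPD1 (4.15-fold), ANKRD9 (4.04-fold, with another probe that did not pass), SH3GL1 (4.03-fold) and STMN3 (3.98-fold). AP1M1 (3.56-fold), IGFBP6 (3.45-fold), the metalloproteinase gene ADAMTS1 (3.44-fold), TXNIP (3.41-fold), CENPB (3.36-fold) and the replication licensing gene CDT1 (3.29-fold) also rose. The adjusted p of these 24 genes ran from 6.45e-07 to 6.4e-04. Groups did not overlap for 7653 genes (64.4%), where chance gives 33.3% for a single gene, with the same limit for the share over genes.

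Cell cycle genes rose nearly throughout with FOXO1 siRNA. In the G2/M list 37 of 38 members rose, 0 fell and 1 did not pass, or 38 changed when adjusted over the list alone, with a median of 1.05 (adjusted p = 5.49e-24, and adjusted p = 0.0612 with an estimated correlation). UBE2C rose 3.15-fold, AURKB 2.96-fold, ECT2 2.69-fold and CENPF 2.54-fold. In the G1/S list 26 of 31 members rose, 0 fell and 5 did not pass, or 26 changed when adjusted over the list alone, with a median of 0.99 (adjusted p = 1.16e-14, and adjusted p = 0.159 with an estimated correlation). MCM4 rose 2.79-fold, GINS2 2.74-fold and MCM5 2.59-fold. In the MYC and ribosome biogenesis list 12 of 25 members rose, 0 fell and 13 did not pass, or 15 changed when adjusted over the list alone (median 0.33, adjusted p = 4.75e-06, and adjusted p = 0.159 with an estimated correlation). The spermidine synthase gene SRM rose 3.10-fold and BOP1 2.21-fold.

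Inflammatory and adhesion genes fell with FOXO1 siRNA. In the NF-kB list 19 of 21 members fell, 0 rose and 2 did not pass, or 19 changed when adjusted over the list alone, with a median of -0.93 (adjusted p = 9.46e-15, and adjusted p = 0.0612 with an estimated correlation). VCAM1 fell 4.97-fold beside SELE, CCL2, CXCL2 and CCL20. In the interferon response list 11 of 33 members fell, 6 rose and 16 did not pass, or 20 changed when adjusted over the list alone, and the list did not pass (median -0.23, adjusted p = 0.247). MX2 fell 1.84-fold and SAMD9L 2.22-fold, while IFI6 rose 1.98-fold with another probe that did not pass.

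Of the lists of vascular genes, those of Notch and arterial genes, tip cells and endothelial identity passed with FOXO1 siRNA. In the Notch and arterial list 13 of 19 members fell, 2 rose and 4 did not pass, or 17 changed when adjusted over the list alone, with a median of -0.83 (adjusted p = 9.29e-06, and adjusted p = 0.159 with an estimated correlation). EFNB2, which encodes the arterial marker ephrin B2, fell 5.01-fold, DLL4 at least 2.50-fold and JAG2 2.15-fold. In the tip cell list 14 of 19 members fell, 1 rose and 4 did not pass, or 16 changed when adjusted over the list alone, with a median of -0.68 (adjusted p = 3.41e-06, and adjusted p = 0.140 with an estimated correlation). ANGPT2, which encodes an antagonist ligand of the TIE2 receptor, fell 3.45-fold and PDGFB 3.47-fold, while IGFBP3 rose 2.47-fold. In the endothelial identity list 16 of 32 members fell, 2 rose and 14 did not pass, or 19 changed when adjusted over the list alone, with a median of -0.38 (adjusted p = 2.12e-05, and adjusted p = 0.212 with an estimated correlation). PLVAP fell 5.68-fold, CD34 4.11-fold with another probe that did not pass, the tight junction gene CLDN5 2.63-fold and PECAM1 2.57-fold. Markers of smooth muscle cells and fibroblasts rose beside these lists, 4 of 7 higher, 0 lower and 3 that did not pass, or 4 changed when adjusted over the list alone (median 0.67, adjusted p = 0.0165, and adjusted p = 0.212 with an estimated correlation). ACTA2 rose 2.38-fold, COL1A2 2.14-fold, LUM at least 1.53-fold and DCN at least 1.29-fold, and the list did not pass with no filter on dim probes (adjusted p = 0.190). Epithelial markers did not pass (2 higher and 0 lower of 8, adjusted p = 0.285).

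Of the FoxO targets and the lipid lists, 3 lists passed with FOXO1 siRNA, each with members that did not pass. In the FoxO target list 10 of 32 members fell, 1 rose and 21 did not pass, or 11 changed when adjusted over the list alone, with a median of -0.21 (adjusted p = 0.00284, and adjusted p = 0.301 with an estimated correlation). The superoxide dismutase gene SOD2 fell 2.48-fold and the autophagy gene MAP1LC3B 2.06-fold beside DEPP1, while TXNIP rose. In the list of fatty acid uptake and binding 9 of 20 members fell, 2 rose and 9 did not pass, or 14 changed when adjusted over the list alone (median -0.32, adjusted p = 0.0156, and adjusted p = 0.301 with an estimated correlation). FABP4 fell 4.24-fold, VLDLR at least 2.71-fold and the endothelial lipase gene LIPG 2.00-fold, and the list did not pass with a stricter filter (adjusted p = 0.0672). In the cholesterol synthesis list 9 of 19 members fell, 0 rose and 10 did not pass, or 9 changed when adjusted over the list alone (median -0.27, adjusted p = 0.0106, and adjusted p = 0.272 with an estimated correlation). SQLE fell 1.87-fold.

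Stress and translation lists also passed with FOXO1 siRNA. Of the endoplasmic reticulum stress list 8 of 17 members fell, 0 rose and 9 did not pass, or 9 changed when adjusted over the list alone (median -0.35, adjusted p = 0.0013, and adjusted p = 0.161 with an estimated correlation), with CRELD2 down 1.86-fold and DNAJB9 1.69-fold. Of the hypoxia list 8 of 15 members fell, 1 rose and 6 did not pass, or 9 changed when adjusted over the list alone (median -0.34, adjusted p = 0.0196, and adjusted p = 0.212 with an estimated correlation), with ERO1A down 1.85-fold and BNIP3L 1.77-fold. Of the heat shock list 6 of 12 members rose, 0 fell and 6 did not pass, or 6 changed when adjusted over the list alone (median 0.35, adjusted p = 0.0146, and adjusted p = 0.272 with an estimated correlation), with HSPA1B up 1.73-fold. Of the ribosomal protein list 4 of 33 members rose, 0 fell and 29 did not pass, or 3 changed when adjusted over the list alone (median 0.12, adjusted p = 0.0305, and adjusted p = 0.212 with an estimated correlation), with RPL37 up 1.63-fold. Without control replicate 2 the hypoxia, heat shock and ribosomal protein lists did not pass (adjusted p up to 0.0511, 0.0557 and 0.0998), nor did the last without FOXO1 siRNA replicate 2 or with an offset of 16. The count of changed genes was 5362 without control replicate 2, and 1529 and 1370 without FOXO1 siRNA replicates 1 and 2.

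The remaining lists did not pass with FOXO1 siRNA, though single members changed. In the list of basement membrane and matrix 12 of 31 members fell and 4 rose (median -0.25, adjusted p = 0.0642), with the metalloproteinase gene MMP10 at a log2 fold change of -1.85, and the list passed with no filter on dim probes (adjusted p = 0.0189). In the autophagy and lysosome list 11 of 25 fell and 4 rose (median -0.26, adjusted p = 0.239), and in the ATF4 list 5 of 19 rose and 4 fell (median 0.16, adjusted p = 0.793). In the list of the KLF2 and MEF2 axis 3 of 13 members rose and 0 fell (median 0.15, adjusted p = 0.153), with the flow-responsive transcription factor gene KLF2 up 2.48-fold and the nitric oxide synthase gene NOS3 2.46-fold. In the vasoactive list 7 of 15 fell and 3 rose (median -0.42, adjusted p = 0.258), with the endothelin gene EDN1 down 1.83-fold. Of the p53 targets 4 of 22 fell and 0 rose (adjusted p = 0.569), with TP53INP1 down 2.63-fold and GDF15 2.08-fold. Of the YAP/TAZ targets 6 of 19 fell and 1 rose (median -0.09, adjusted p = 0.153), with CCN1 down 2.18-fold. Of the immediate early genes 4 of 14 fell and 2 rose (adjusted p = 0.674), with IER3 down 3.66-fold. Glycolysis genes gave 3 lower and 2 higher of 20 (adjusted p = 0.793), with the glucose transporter gene SLC2A3 down 2.76-fold. The lists of venous and lymphatic genes (3 lower and 1 higher of 7, adjusted p = 0.557), FGF signalling (5 lower and 2 higher of 18, adjusted p = 0.674), fatty acid oxidation (2 lower and 2 higher of 17, adjusted p = 0.939) and oxidative phosphorylation (4 higher and 0 lower of 33, adjusted p = 0.569) did not pass. Neither did endothelial genes linked to FOXO1 (4 higher and 4 lower of 11, adjusted p = 0.608), TGF-beta and mesenchymal transition (3 higher and 1 lower of 20, adjusted p = 0.939) or blood cell markers (2 lower and 0 higher of 6, adjusted p = 0.793).

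For some lists the median, the mean and the direction of the test differed in sign. With FOXO1 siRNA the median lay above 0 while the mean and the test pointed down for endothelial genes linked to FOXO1 (0.04 and -0.25), p53 targets (0.06 and -0.17), glycolysis (0.04 and -0.06), immediate early genes (0.08 and -0.16) and blood cell markers (0.01 and -0.05). For TGF-beta and mesenchymal transition the median was -0.15, the mean 0.02 and the test pointed down. With APLN/APLNR siRNA this was so for fatty acid uptake and binding (median 0.09, mean -0.02, test down), venous and lymphatic genes (median -0.08, mean 0.07, test up), vasoactive mediators (median 0.02, mean -0.03, test up) and glycolysis (median -0.04, mean 0.002, test down). None of these lists passed.

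**Figure D2:**
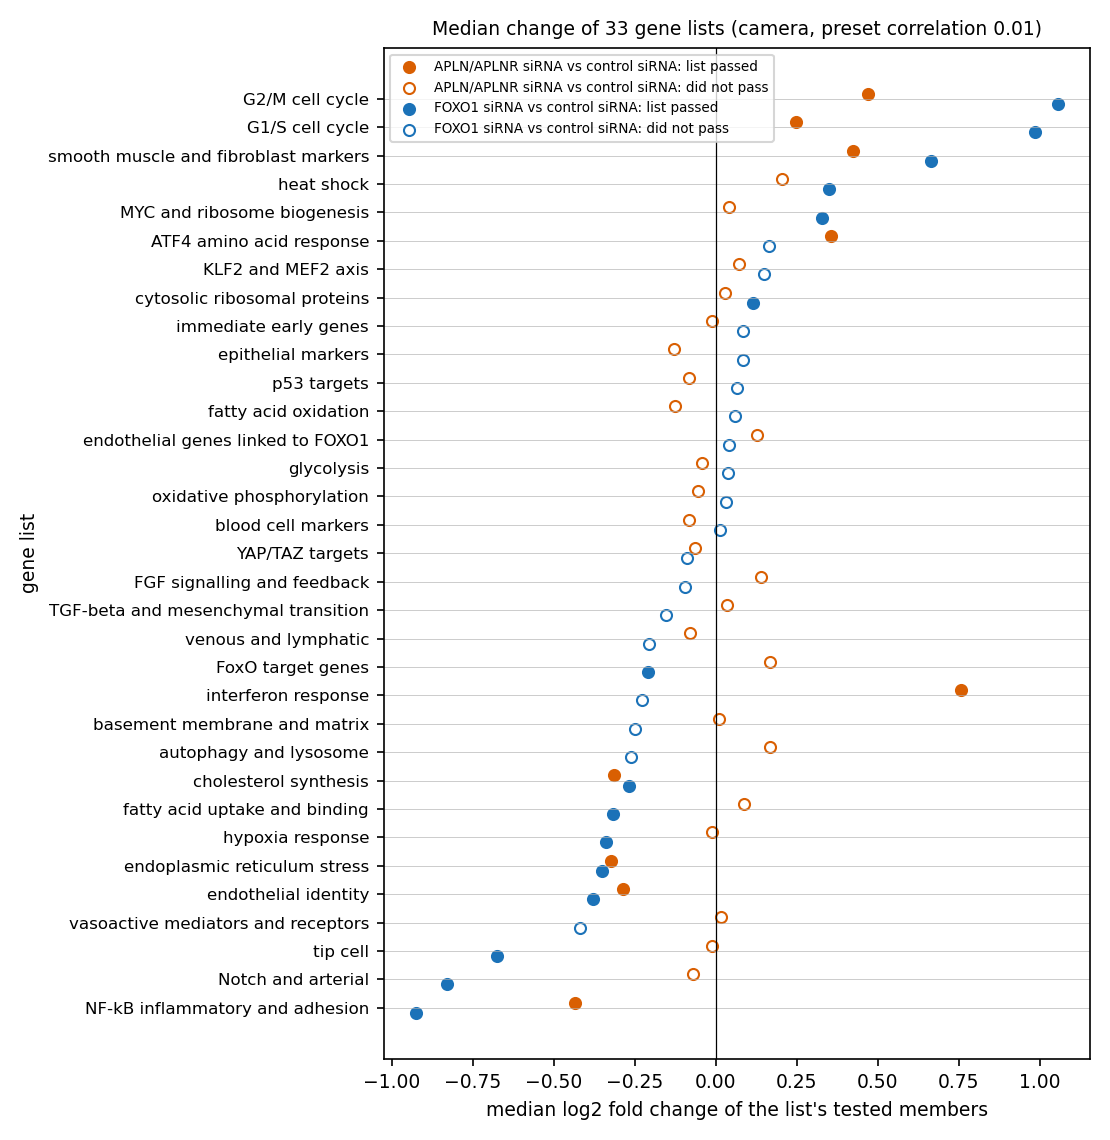
Median log2 fold change (horizontal axis) of the tested members of 33 gene lists (vertical axis) with APLN/APLNR siRNA (orange) and FOXO1 siRNA (blue) against control siRNA; filled points passed camera with the preset correlation and open points did not. The interferon response has medians of 0.76 and -0.23, and the NF-kB list -0.44 and -0.93.

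The title of the series sets FoxO1 as inhibited by apelin signalling, which raises the question whether the knockdowns moved genes in opposite directions. FABP4 rose with APLN/APLNR siRNA and fell with FOXO1 siRNA (log2 fold changes 1.73 and -2.09, SE 0.11 for both), as did DEPP1 (0.91 and -3.06), MX2 (1.77 and -0.88), CXCR4 (2.26 and -0.80), ESM1 (0.95 and -0.89), GBP1 (0.91 and -0.89), the matrix gene MGP (0.82 and -0.93) and TSPAN7 (0.80 and -1.28). The other way round were ADAMTS18 (at least 1.69-fold lower, then 2.85-fold higher), RGS4 (-0.88 and 2.17), the lipid phosphatase gene PLPP3 (-1.16 and 0.74), LHX6 (-0.66 and 1.59), TMEM97 (-0.67 and 1.02), ZNF467 (-0.82 and 1.01), OIP5 (-0.64 and 0.72) and WDFY1 (-0.77 and 0.54). Another probe did not pass with APLN/APLNR siRNA for GBP1, ADAMTS18, PLPP3, TMEM97 and OIP5, and another probe of TMEM97 changed in the opposite direction with FOXO1 siRNA. In 1 or both knockdowns the calls on DEPP1, ESM1, CXCR4, TSPAN7, RGS4, LHX6, TMEM97, ZNF467, OIP5 and WDFY1 were lost when an array of that knockdown was left out. Those on TSPAN7 and ZNF467 with APLN/APLNR siRNA were also lost with no background correction and with only the arrays compared, and that on ZNF467 with a stricter filter. In all, 129 genes changed in opposite directions, 97 of them higher with APLN/APLNR siRNA, where independent lists of these sizes would give 347.6 (184.1 for the 97).

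Far more genes changed in the same direction. Genes were ranked by the smaller of their 2 absolute log2 fold changes. By this rank SELE, LTB, CCL20 and CYTL1 led the 644 genes that fell in both knockdowns (172.2 if independent), and LYPD1, TXNIP, AP1M1 and SH3GL1 led the 619 that rose in both (174.8 if independent). SH3GL1 lost its call with APLN/APLNR siRNA without APLN/APLNR siRNA replicate 1 (adjusted p = 0.0579). Unchanged groups simulated against shared controls gave 0 genes in opposite directions, and in the same direction 0.02 genes with pooled SDs and 0.24 with each group's own SDs. These sets hold no true change, so hardly any gene can pass in them, and their counts are no reference for those observed. The counts given for independent lists, here and for opposite directions, take no account of the shared control arrays. Across genes, the covariance of the 2 sets of log2 fold changes was 0.0940. Simulated values were 0.00836 with pooled SDs and 0.0212 with each group's own SDs, which leaves differences of 0.0857 and 0.0728. The correlation of 0.558 lay above the 0.499 simulated with pooled SDs and below the 0.797 simulated with each group's own SDs, and 69.6% of genes had the same sign (simulated 66.7% and 73.9%). True changes that differ between the knockdowns would lower both values, so the simulated correlations and shares are no reference either. The control arrays could not be split into parts of 2, and part of the excess in covariance may come from them. With a separate control array for each knockdown the covariance was 0.0663 and 0.0793. The correlation was then 0.350 and 0.426, and 57.4% and 62.0% of genes had the same sign. The count in opposite directions was 232 and 209 without control replicates 1 and 2, 36 and 37 without APLN/APLNR siRNA replicates 1 and 2, 40 and 31 without FOXO1 siRNA replicates 1 and 2, and 61 with only the arrays compared. The count in the same direction was 2894 without control replicate 2, 445 and 419 without APLN/APLNR siRNA replicates 1 and 2, 594 and 570 without FOXO1 siRNA replicates 1 and 2, and 806 with only the arrays compared. The covariance was 0.146 without control replicate 2 and 0.0585 with no filter on dim probes.

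**Figure D3:**
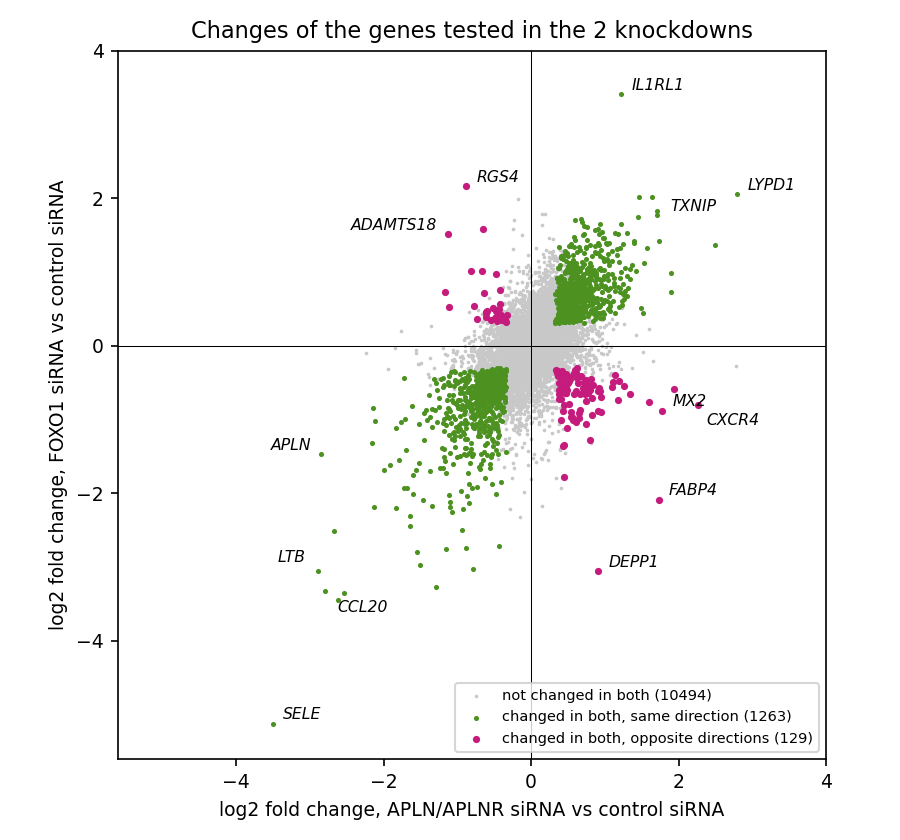
Log2 fold change with FOXO1 siRNA (vertical axis) against that with APLN/APLNR siRNA (horizontal axis), both against control siRNA, for 11886 genes. Green points changed in both knockdowns in the same direction (1263 genes), pink points in opposite directions (129 genes) and grey points did not change in both.

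In the direct comparison of FOXO1 siRNA with APLN/APLNR siRNA (n = 2 arrays per group) the fold changes use no control array, while the error of each gene comes from all 6 arrays. Of 33 lists 13 passed, and 0 with an estimated correlation, with interferon-induced, inflammatory and FoxO target genes among those lower with FOXO1 siRNA and cell cycle genes among those higher. DEPP1 was 15.7-fold lower with FOXO1 siRNA (SE 0.14 on the log2 scale), FABP4 14.1-fold lower (SE 0.11), CXCR4 8.35-fold lower (SE 0.17) and MX2 6.28-fold lower (SE 0.13). RGS4 was 8.28-fold higher (SE 0.15), ADAMTS18 at least 4.81-fold higher (SE 0.12), the homeobox gene LHX6 4.73-fold higher (SE 0.16) and IL1RL1 4.60-fold higher (SE 0.13). In all, 2611 of 11886 genes differed, 1206 higher and 1405 lower with FOXO1 siRNA, with 88 higher and 225 lower by over 2-fold. At an unadjusted p under 0.05 there were 4053.

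Also lower with FOXO1 siRNA than with APLN/APLNR siRNA were CCL23 (at least 7.52-fold), RASD1 (5.77-fold), TMEM140 (5.15-fold), RAB8B (5.04-fold), the scavenger receptor gene COLEC12 (4.99-fold) and C2CD4B (4.85-fold). Higher were STMN3 (4.50-fold), SUMF1 (4.39-fold), ARPC1A (3.93-fold), the small nucleolar RNA gene SNORD3A (3.84-fold), PLPP3 (3.73-fold) and ZNF467 (3.55-fold). Groups did not overlap for 8113 genes (68.3%), where chance gives 33.3% for a single gene, with the same limit for the share over genes. The count of genes that differed was 4566 without either control array or with only the arrays compared, 1096 and 911 without APLN/APLNR siRNA replicates 1 and 2, and 984 and 901 without FOXO1 siRNA replicates 1 and 2.

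In the interferon response list 28 of 33 members were lower with FOXO1 siRNA, 0 higher and 5 did not pass, or 30 differed when adjusted over the list alone (median -0.85, adjusted p = 4.25e-18, and adjusted p = 0.158 with an estimated correlation). RSAD2 was 3.99-fold lower and EPSTI1 3.17-fold lower. FoxO targets were lower for 18 of 32 members, higher for 0 and did not pass for 14, or differed for 21 when adjusted over the list alone (median -0.39, adjusted p = 8.48e-07, and adjusted p = 0.221 with an estimated correlation). SOD2 was 2.91-fold, FBXO32 2.88-fold and GADD45B 2.74-fold lower. The NF-kB list was lower for 13 of 21 members, higher for 0 and did not pass for 8, or differed for 15 when adjusted over the list alone (median -0.52, adjusted p = 6.68e-10, and adjusted p = 0.115 with an estimated correlation), with CCL2 4.72-fold and CXCL10 3.67-fold lower. The autophagy and lysosome list was lower for 8 of 25 members, higher for 0 and did not pass for 17, or differed for 12 when adjusted over the list alone (median -0.26, adjusted p = 9.98e-04, and adjusted p = 0.268 with an estimated correlation), with SQSTM1 1.95-fold lower.

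Division genes were higher with FOXO1 siRNA than with APLN/APLNR siRNA. In the G2/M list 30 of 38 members were higher, 0 lower and 8 did not pass, or 33 differed when adjusted over the list alone (median 0.65, adjusted p = 1.36e-16, and adjusted p = 0.115 with an estimated correlation), with TPX2 2.37-fold higher. In the G1/S list 19 of 31 were higher, 0 lower and 12 did not pass, or 24 differed when adjusted over the list alone (median 0.80, adjusted p = 4.16e-13, and adjusted p = 0.158 with an estimated correlation), with GINS2 2.31-fold higher. In the MYC and ribosome biogenesis list 9 of 25 were higher, 0 lower and 16 did not pass, or 12 differed when adjusted over the list alone (median 0.34, adjusted p = 5.98e-06, and adjusted p = 0.158 with an estimated correlation), with RRS1 1.67-fold higher.

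Tip cell and arterial genes were lower with FOXO1 siRNA than with APLN/APLNR siRNA. In the Notch and arterial list 10 of 19 members were lower, 1 higher and 8 did not pass, or 11 differed when adjusted over the list alone (median -0.54, adjusted p = 1.66e-05, and adjusted p = 0.158 with an estimated correlation), with EFNB2 4.53-fold lower. In the tip cell list 12 of 19 were lower, 2 higher and 5 did not pass, or 15 differed when adjusted over the list alone (median -0.48, adjusted p = 2.71e-04, and adjusted p = 0.158 with an estimated correlation), with PDGFB 4.37-fold and ESM1 3.58-fold lower. The tested members of this list include APLN, itself a target of APLN/APLNR siRNA and at a higher level with FOXO1 siRNA. The endothelial identity list had 12 of 32 lower, 3 higher and 17 that did not pass, or 16 that differed when adjusted over the list alone (median -0.21, adjusted p = 0.0361, and adjusted p = 0.429 with an estimated correlation), with SOX17 2.83-fold lower and GATA2 1.94-fold higher. The smooth muscle and fibroblast markers beside it did not pass (3 higher and 1 lower of 7, adjusted p = 0.376).

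Basement membrane and matrix genes were lower for 9 of 31 members, higher for 4 and did not pass for 18, or differed for 19 when adjusted over the list alone (median -0.26, adjusted p = 0.0259, and adjusted p = 0.266 with an estimated correlation), with MGP 3.37-fold and SPARC 3.07-fold lower and ADAMTS1 3.01-fold higher. The ATF4 list had 7 of 19 lower, 3 higher and 9 that did not pass, or 10 that differed when adjusted over the list alone (median -0.23, adjusted p = 0.0361, and adjusted p = 0.409 with an estimated correlation), with SLC7A11 2.40-fold lower. Epithelial markers had 3 of 8 higher, 0 lower and 5 that did not pass, or 4 that differed when adjusted over the list alone (median 0.26, adjusted p = 0.0381, and adjusted p = 0.268 with an estimated correlation), with the keratin gene KRT19 1.98-fold higher. The calls on the lists of endothelial identity, basement membrane and ATF4 were lost with a stricter filter, that on epithelial markers with no filter, and all but that on basement membrane also when single knockdown arrays were left out (adjusted p up to 0.117, 0.249, 0.107 and 0.0871). The cholesterol synthesis list, which did not pass (adjusted p = 0.764), had a median of 0.03 and a mean of -0.04 with the test pointing down. TGF-beta genes (median -0.08, mean 0.02, test down) and immediate early genes (median 0.05, mean -0.13, test down) did not pass either.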

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

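The gene lists, the covariance and the leaving out of single arrays were fixed before the data were examined, while the simulations with each group's own spread, the separate control arrays and the use of these values as tests of explanations were chosen after the results were seen. Probes with no gene symbol stood outside the gene counts, and of 5052 such probes above background 236 changed with APLN/APLNR siRNA, 511 with FOXO1 siRNA and 397 between the knockdowns.

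The first pattern is that 1263 genes changed in the same direction in both knockdowns and 129 in opposite directions, with SELE, CCL20 and CYTL1 among the lower ones. The covariance argues against chance values of the shared control arrays as the whole cause, since the arrays' own spread gives 0.0212 against 0.0940 observed, and 0.0663 and 0.0793 with a separate control array for each knockdown. The correlation (0.558) and the share of genes with the same sign (69.6%) lay below those simulated with each group's own SDs (0.797 and 73.9%). Those sets hold no true change, and changes that differ between the knockdowns would lower both values. The correlation and the share of signs therefore cannot decide on this explanation. The covariance also argues against control replicate 1 as the whole cause, since without it the value was 0.0841, above the highest value of 0.0454 simulated for unchanged groups and 1 control array. APLN itself fell with FOXO1 siRNA (log2 fold change -1.47), so loss of apelin in both knockdowns could account for part of the pattern, but no array has FOXO1 siRNA with apelin restored. An effect of targeting siRNAs against control siRNA likewise cannot be told apart from the targets, since each target had 1 siRNA group.

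The second pattern is the rise of interferon response genes, such as IFI6, MX2 and IFITM1, with APLN/APLNR siRNA. A response of the same size to both sets of targeting siRNAs is argued against as the whole cause, since 28 of 33 members were lower with FOXO1 siRNA than with APLN/APLNR siRNA and 0 were higher. Such a response is not excluded in itself, since a fall of these genes after loss of FOXO1 would give the same difference. A smaller shared response of some members stays open, since 6 members rose with FOXO1 siRNA and 11 fell, with IFI6 (log2 fold change 0.99) and IFITM1 (0.45, a call lost in 7 alternatives) among those that rose. The list differed between the knockdowns (median -0.85, camera adjusted p = 4.25e-18, and adjusted p = 0.158 with an estimated correlation). An effect of the sequence or amount of the APLN and APLNR siRNAs would give this, and loss of the targets would give it too. These cannot be told apart with 1 set of siRNAs for these targets, and a dependence of the genes on apelin signalling stays untested.

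The third pattern is that the endothelial identity list was lower in both knockdowns and the list of smooth muscle and fibroblast markers higher, calls lost with an estimated correlation (adjusted p = 0.646 and 0.436 with APLN/APLNR siRNA, 0.212 and 0.212 with FOXO1 siRNA). A smaller share of endothelial RNA would not by itself raise these genes. Of 32 endothelial identity members, 3 were higher with APLN/APLNR siRNA, ENG among them, and 2 with FOXO1 siRNA. The 2 were GATA2, whose call held in all alternatives run, and ENG, whose call was lost in 4. So few members cannot decide on a change of share, since other cells could express them, which was not tested. Of the 7 smooth muscle and fibroblast members tested, 3 were higher in both knockdowns (COL1A2, DCN and LUM), but DCN and LUM reached background on 4 of 6 arrays and the call on LUM with APLN/APLNR siRNA (log2 fold change 0.36, adjusted p = 0.0422) was lost in 7 of 14 alternatives. COL1A1, PDGFRA, PDGFRB, THY1, MYH11, CNN1 and DES were above background on 0 of 6 arrays. ACTA2, TAGLN, COL1A2 and RGS5 reached it on 6 of 6 arrays, and COL3A1 on 4. Since markers of the same list went both ways, they do not show how many smooth muscle cells or fibroblasts were in the cultures. Such cells cannot be told apart from expression of the markers by endothelial cells, and a few could go undetected by these probes. A change of endothelial state after loss of each target was not tested.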

How the results depend on the processing

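The crossed numbering was chosen after seeing the data, and all other alternatives were fixed before. No named gene or list call reversed under any alternative run. Of 549 calls on named genes, 340 held under every alternative and 209 were lost under at least 1. Of 37 list calls, 25 held under every alternative with the preset correlation. With an estimated correlation 0, 0 and 0 lists passed with APLN/APLNR siRNA, with FOXO1 siRNA and between the knockdowns (9, 15 and 13 with the preset). The covariance of the knockdowns' fold changes was 0.129 with an offset of 16 and 0.0585 with no filter on dim probes, against 0.0940; the cause was not tested. With only the arrays of the groups compared, 1539 genes changed with APLN/APLNR siRNA, 4566 differed between the knockdowns, 61 changed in opposite directions and 806 in the same direction, as the spread then comes from those arrays alone.

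The arrays of the groups share replicate numbers, which the labels do not explain. With a replicate block 1893, 2892 and 2085 genes changed in the 3 comparisons, and 83 in opposite directions, against 129. Deviations of same-numbered arrays correlated at -0.336 between control and APLN/APLNR siRNA; with the numbers of APLN/APLNR siRNA crossed, 2691, 3761 and 2905 genes changed.

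Without 1 array, the count ran from 705 to 4419 with APLN/APLNR siRNA, 1370 to 5362 with FOXO1 siRNA, 901 to 4566 between the knockdowns, 31 to 232 in opposite directions and 419 to 2894 in the same direction, and the covariance from 0.0841 to 0.146. A lone array left in a group was assumed to vary like those of the other groups. APLN fell with APLN/APLNR siRNA under every alternative run (-3.16 to -2.52), as did FOXO1 with its siRNA (-1.21 to -0.91). Correction with detection p-values and a slide block were not run. Median scaling moved little, since the deposited values already share a distribution. APLNR lay below background on the control arrays, which limits what can be said of it.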

Other observations

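The symbol families, their tests and the separate control arrays were chosen after the results were seen, while the FoxO target list and its test were fixed before the data were examined. The chemokine family was lower in both knockdowns by its test, with exceptions. It shares genes such as CCL2, CXCL2 and CCL20 with the NF-kB list, so it is not separate evidence from that list. With FOXO1 siRNA 15 of 18 tested were lower, 1 higher and 2 did not pass (median -1.41, adjusted p = 6.82e-11, and adjusted p = 0.142 with an estimated correlation), and with APLN/APLNR siRNA 10 were lower, 2 higher, CCL23 among them, and 6 did not pass (median -0.65, adjusted p = 0.0128, and adjusted p = 0.523 with an estimated correlation). CXCL5 fell in both (log2 fold changes -1.68 with APLN/APLNR siRNA and -1.93 with FOXO1 siRNA), as did CCL7 (-1.37 and -1.70). HLA class I and related genes were higher for 5 of 9 with APLN/APLNR siRNA (adjusted p = 0.0210, and adjusted p = 0.583 with an estimated correlation) and lower for 4 of 9 with FOXO1 siRNA (adjusted p = 0.0107, and adjusted p = 0.380 with an estimated correlation), with HLA-B at 1.18 and -0.74. Of 6 genes of guanylate-binding proteins 3 were higher and 0 lower with APLN/APLNR siRNA (adjusted p = 0.0210, and adjusted p = 0.523 with an estimated correlation) and 3 lower and 0 higher with FOXO1 siRNA (adjusted p = 0.00679, and adjusted p = 0.223 with an estimated correlation), with GBP4 at 1.26 and -0.54. In the direct comparison 7 of 9 HLA genes were lower with FOXO1 siRNA (adjusted p = 5.03e-06, and adjusted p = 0.330 with an estimated correlation), as were 4 of 6 of the others (adjusted p = 4.32e-05, and adjusted p = 0.263 with an estimated correlation).

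With FOXO1 siRNA 23 of 109 small nucleolar RNAs were higher, 3 lower and the others did not pass (adjusted p = 4.57e-05, and adjusted p = 0.223 with an estimated correlation), with SNORD3A up by 1.71 and SNORD3D by 1.59 on the log2 scale. Kinesin genes were higher for 13 of 26 and lower for 3 (adjusted p = 0.00499, and adjusted p = 0.223 with an estimated correlation), with the mitotic kinesin gene KIF2C up by 1.33. KIF2C and other kinesin genes are also members of the G2/M list, so this family is not separate evidence from that list. Metallothionein genes were lower for 4 of 7 and higher for 0 (adjusted p = 0.00679, and adjusted p = 0.223 with an estimated correlation), with MT1F at -1.65. Between the knockdowns, vacuolar ATPase subunit genes were lower with FOXO1 siRNA for 6 of 19 and higher for 0 (adjusted p = 0.00339, and adjusted p = 0.263 with an estimated correlation). Of 30 families, 4, 11 and 10 passed in the 3 comparisons, and 0 with an estimated correlation.

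A hypothesis from the title of the series is that loss of apelin signalling releases FoxO1, so that genes lowered by FOXO1 siRNA would be raised by APLN/APLNR siRNA. Since both knockdowns share the control arrays, this was examined with a separate control array for each, as values with no significance test. Of 367 genes lower by over 2-fold with FOXO1 siRNA against control replicate 1, 109 were higher with APLN/APLNR siRNA against control replicate 2 (29.7%) and 258 lower. With the control arrays exchanged, 46 of 243 were higher (18.9%) and 197 lower. Most of these genes were thus not raised by APLN/APLNR siRNA. This cannot decide whether FoxO1 was released, since knockdown of APLNR could not be measured. A fall shared by both sets of targeting siRNAs could also hide a rise. Of 32 FoxO targets 9 were higher and 0 lower with APLN/APLNR siRNA, where the list did not pass (adjusted p = 0.0630). With FOXO1 siRNA 10 were lower and 1 higher. In the direct comparison 18 were lower with FOXO1 siRNA and 0 higher (adjusted p = 8.48e-07, and adjusted p = 0.221 with an estimated correlation). Its fold changes use no control array, though its errors do. The direct comparison cannot show release, since a fall with FOXO1 siRNA alone would give such values. No array combined the knockdowns.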
